A study of Homo sapiens with 9 samples.

How the data were processed

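Gene expression was measured in A375P, an established human melanoma cell line, after 2, 6 or 24 h with the solvent DMSO, with 1 µM of PD184352, an inhibitor of the MEK kinases, or with 0.4 µM of PLX4720, a RAF kinase inhibitor. There were 9 deposited columns, 1 for each of the 9 combinations of treatment and time. The text on the series design speaks of triplicates. Whether a column is 1 array or an average over triplicates is not given in the sources used here, and a column is called an array in what follows. No group had more than 1 column. The array was a gene-level exon array, on which each row is a transcript cluster.

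The deposited values are intensities on a linear scale, as the authors gave them: every value was positive, and the median intensity per array lay between 98.96 and 102.4. The submitters' processing notes name RMA, limma and R 2.8.0 without their role or order. The genome build is not given in the sources used here, so no coordinates are printed. For arrays, their number limits the precision, and no depth of counting applies.

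From the deposited intensities, log2(value + 1) was computed, and changes are differences on that scale, which understates the change of dim genes. No further normalization was applied. Of 35446 rows, 19380 had 1 gene symbol in the platform table, 3339 had several and 12727 were not in it. Rows without exactly 1 symbol were left out of the main tests. Names were checked through the gene identifier against a RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols changed. For the 1794 genes with more than 1 row, the row with the highest mean over the 9 arrays was used. Of 17047 genes, the 4262 with the lowest means (25%) were left out, and 12785 were tested. No pair of arrays held identical values (0 pairs). Genes without a row that names 1 gene, among them the target kinases of both compounds, are not analysed here.

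All tests used limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. A first fit had treatment and, as a block, time (residual degrees of freedom 4), and gave the change with either inhibitor, with each inhibitor, and between the inhibitors, as means over the 3 times. In this fit a response that varies with time adds to the spread. A second fit compared the mean of both inhibitor arrays with the DMSO array at each time (residual degrees of freedom 3). In that fit the spread comes from the difference between PD184352 and PLX4720 at the same time. They are different compounds and not replicates, and each DMSO array stands alone, so the p-values measure that spread and not the spread between cultures. An F-test in the second fit asked whether the change differed between times. Standard errors (SE) are limma's moderated ones.

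A set of 28 gene lists (508 genes, of which 424 had a row and 376 were tested, with 14 genes in more than 1 list) was fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The size of the estimated correlation is not the only reason that lists lose their call there. For immediate-early genes at 2 h it was −0.003, below the preset, and camera's unadjusted p still went from 1.8e-13 to 0.00397. A list that did not hold is therefore not shown to have lost its call through correlation between genes. Counts of changed members are given over all genes tested and adjusted over the list alone. The genes named were chosen by a rule also fixed then: the 10 largest falls and rises with either inhibitor whose 6 differences had 1 sign, the 5 largest each way at each time with 1 sign for both inhibitors, the 5 largest each way between inhibitors, the 5 largest differences each way between 24 h and 2 h by the F-test, all ERK feedback genes, up to 4 genes of each other list by size of the mean change, and the drug targets. Fewer are named where fewer passed.

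Both fits were tested on simulated data with the real means and each fit's own spread, with 200 of 12785 genes changed. For the mean over 3 times with either inhibitor, 92% of genes changed by 0.5 (log2) and 100% of those changed by 1 were recovered, with 10 unchanged genes called. At 24 h these shares were 94% and 100%, with 17 unchanged genes called. For PD184352 against PLX4720 they were 80% and 100%, with 9 unchanged genes called. Noise was drawn alike for all arrays from each fit's spread, so variation between cultures beyond that spread is left out. The 200 changed genes are also far fewer than the 4045 called at 24 h in the real data. The numbers of unchanged genes called therefore do not carry over to the real tests. The simulated changes in the first fit were equal at all times, so these shares do not hold for a change that varies with time: SPRY4, at a mean of −3.38 (adjusted p = 0.0585), and ERRFI1, at −2.10 (adjusted p = 0.0964), were not called.

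The alternatives tried were no filter on dim genes, a filter of 50%, quantile normalization, median centring, the average of a gene's rows, a variance trend, robust moderation, array weights, a threshold of 0.01, no time block, and leaving out each array and each time. Other pseudocounts, a fit without the 24 h arrays, the DMSO 6 h array as control at 24 h and a fit between the compounds on the 6 inhibitor arrays alone (residual degrees of freedom 2) were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.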

Results

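Transcript levels were measured in A375P melanoma cells, an established line that carries a mutant RAF kinase, on 9 arrays: DMSO, 1 µM PD184352 and 0.4 µM PLX4720, each at 2, 6 and 24 h. The series asks which genes respond directly to the mutant kinase and to MEK, the kinase below it in the pathway that ends in ERK. There was 1 array per treatment and time, no separate replicate values were analysed here, and median intensities lay between 98.96 and 102.4. The 99th percentile of intensity was 1681 to 1754 on the DMSO arrays and 1550 to 1654 on the inhibitor arrays. The upper end of the intensities was thus lower with inhibitor at every time. How far this adds to the excess of lower over higher calls was not tested. In DMSO cells, 0 of 12785 genes differed 2-fold between 6 h and 2 h, and 6 did between 24 h and 2 h. PD184352 arrays differed 2-fold from the DMSO array of the same time in 5 genes at 2 h, 59 at 6 h and 578 at 24 h. PLX4720 arrays did so in 6, 49 and 440 genes. These single-array counts have no test.

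At 24 h, genes of DNA replication and mitosis fell together with both inhibitors against DMSO. All 29 tested DNA replication genes fell, with a median log2 change of −1.28, among them MCM10, a replication initiation factor (−2.05, SE 0.21), CDC45, part of the replicative helicase (−2.01, SE 0.19), RFC3, a subunit of the clamp loader (−1.86, SE 0.16), and POLE, a replicative polymerase subunit (−1.67, SE 0.12). All 27 tested mitosis genes fell, with a median of −1.29, including the kinase CDK1 (−2.26, SE 0.13), the spindle motor KIF11 (−1.88, SE 0.11), the checkpoint kinase TTK (−1.87, SE 0.13) and the kinetochore gene NUF2 (−1.74, SE 0.11). Adjusted over the list alone, the counts were again 29 and 27. Of 10 G1 cyclins and kinases, 9 fell (10 adjusted over the list alone), with CDC25A at −2.07 (SE 0.19), CCNE2 at −1.83 (SE 0.12), cyclin D1 (CCND1) at −1.80 (SE 0.16) and CDK6 at −1.20 (SE 0.11). Each value is the mean of 2 inhibitor arrays against 1 DMSO array, and the changes are in the same direction for both inhibitors.

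Genes of ribosome biogenesis and of a joint list of amino acid synthesis and the unfolded protein response also fell at 24 h. Of 22 ribosome biogenesis genes 20 fell (20 adjusted over the list alone), with RRS1 at −1.18 (SE 0.13), NOLC1 at −1.11 (SE 0.10) and POLR1B, a subunit of RNA polymerase I, at −0.97 (SE 0.11). Of 18 genes of amino acid synthesis and the unfolded protein response 11 fell (11 lower and 1 higher adjusted over the list alone), with the cystine transporter SLC7A11 at −2.23 (SE 0.11), CHAC1 at −1.96 (SE 0.10) and the amino acid transporter SLC7A5 at −1.28 (SE 0.11). Camera with its preset correlation called DNA replication (adjusted p = 2.0e-20), mitosis (adjusted p = 2.2e-23), G1 genes (adjusted p = 2.4e-07) and ribosome biogenesis (adjusted p = 1.4e-09). It also called the joint list of amino acid synthesis and the unfolded protein response (adjusted p = 8.7e-05). The adjusted p was 0.364 for DNA replication and G1 genes, 0.360 for mitosis, 0.377 for ribosome biogenesis and 0.428 for the joint list with an estimated correlation, and 0 of 28 lists held at 24 h. Fry, which tests whether a list's genes move one way on balance and does not set them against other genes, called 12 of 28 lists at 24 h, 3 at 6 h and 1 at 2 h, with an adjusted p of 0.00766 for mitosis and 0.0113 for DNA replication at 24 h.

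Some melanocyte, FOXO target and p53 target genes rose at 24 h. Of 11 melanocyte genes 6 rose (6 adjusted over the list alone) and none fell, with the pigment-cell antigen MLANA at 0.67 (SE 0.10), EDNRB at 0.57 (SE 0.12) and PMEL at 0.44 (SE 0.11), while the lineage factor MITF was at 0.22 (SE 0.10), which did not pass. PMEL was lower, at −0.31, when the DMSO 6 h array served as the control. Of 16 FOXO targets 11 rose and 1 fell (11 and 1 adjusted over the list alone), with CITED2 at 1.30 (SE 0.10) and SESN3 at 1.13 (SE 0.10), against TRIB1 at −1.12 (SE 0.12). Of 15 p53 targets 7 rose and 1 fell (7 and 1 adjusted over the list alone), with TP53INP1 at 2.22 (SE 0.18) and TP53I3 at 0.92 (SE 0.09), against PLK3 at −0.50 (SE 0.09), which turned to 0.12 when all of its rows were averaged. The camera adjusted p was 0.00498 for melanocyte genes, 6.6e-05 for FOXO targets and 0.0266 for p53 targets, and the adjusted p was 0.360, 0.360 and 0.679 with an estimated correlation.

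Most feedback genes were still lower at 24 h. Of the 10 feedback genes 9 were lower (9 adjusted over the list alone), and all 10 MAPK activity genes fell (10 adjusted over the list alone), with a median of −2.21, among them SPRY2 (−2.61, SE 0.51) and DUSP6 (−2.84, SE 0.56). Of 21 immediate-early genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with IER3 at −1.42 (SE 0.13), EGR1 at −1.33 (SE 0.11), KLF4 at −1.03 (SE 0.11) and JUN, a subunit of AP-1, at 2.29 (SE 0.12). The camera adjusted p was 5.1e-05, 2.4e-08 and 0.0120 for these lists, and the adjusted p was 0.360, 0.364 and 0.360 with an estimated correlation.

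The largest falls at 24 h among called genes were in SPRY4 (−4.06, SE 0.25), the ETS factors ETV5 (−3.25, SE 0.14) and ETV4 (−3.12, SE 0.14), lipoprotein lipase LPL (−3.01, SE 0.20) and the receptor gene MRGPRX4 (−2.91, SE 0.19), whose close paralog MRGPRX3 was at −2.80 (SE 0.17). Signal shared between these paralogs was not examined. The largest rises were in ANGPTL7, a secreted angiopoietin-like protein (4.21, SE 0.17), the ATP-gated channel P2RX7 (2.83, SE 0.11), the semaphorin SEMA3D (2.60, SE 0.16), the collagen receptor subunit ITGA2 (2.51, SE 0.11) and the matricellular gene CCN3 (2.35, SE 0.13). In all, 4045 of 12785 genes were called by limma at 24 h, 1595 higher and 2450 lower, 508 of them at least 2-fold. The spread in this test is that between the 2 compounds, not between cultures. Leaving out any 1 array other than DMSO 24 h, without which there is no control, moved the count by less than 1.5 times.

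**Figure D1:**
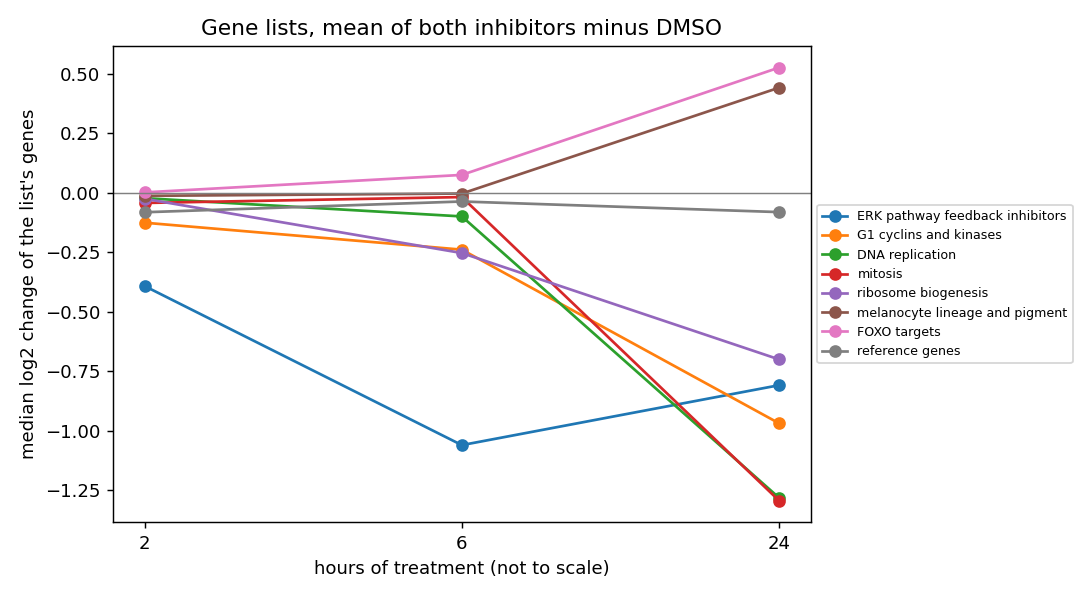
Median log2 change of the genes in 8 of the 28 lists at 2, 6 and 24 h (horizontal axis, hours, not to scale), as the mean of both inhibitor arrays minus the DMSO array. At 24 h, mitosis (−1.29) and DNA replication (−1.28) lie below the other lists drawn, and at 6 h the ERK feedback list (−1.06) does, while the MAPK activity list, not drawn, was lower at both times (−2.21 and −1.50).

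At 6 h, the inhibitors of the ERK pathway that ERK itself induces were low with both compounds. Of the 10 feedback genes 9 fell (10 adjusted over the list alone), led by SPRY4 (−4.13, SE 0.25), the ERK phosphatase DUSP6 (−3.64, SE 0.56) and SPRY2 (−3.25, SE 0.51), with SPRED2 at −1.21 (SE 0.16), SPRED1 at −1.10 (SE 0.17), DUSP4 at −1.02 (SE 0.09), DUSP5 at −0.84 (SE 0.08), DUSP7 at −0.60 (SE 0.09) and SPRY1 at −0.42 (SE 0.09). SPRED3, at −0.20 (SE 0.08), did not pass. All 10 genes of a MAPK activity list fell (10 adjusted over the list alone), with a median of −1.50, of which SPRY2, SPRY4, DUSP4 and DUSP6 are feedback genes too, with EPHA4 at −1.60 (SE 0.10), ETV5 at −1.55 (SE 0.14) and CCND1 at −1.45 (SE 0.16). Of 21 immediate-early genes 9 fell (13 lower and 1 higher adjusted over the list alone), with IER3 at −1.88 (SE 0.13), FOSL1 at −1.62 (SE 0.10) and EGR1 at −1.22 (SE 0.11). The EGFR inhibitor ERRFI1 fell by 2.48 (SE 0.12) on the log2 scale and the growth factor TGFA by 2.22 (SE 0.09). The rises were smaller: SLITRK6 (1.07, SE 0.15), CITED2 (1.03, SE 0.10), SEMA3D (1.02, SE 0.16), the noncoding LINC01531 (0.97, SE 0.18) and the BCL2-family gene BMF (0.91, SE 0.17).

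limma called 420 genes at 6 h, 70 higher and 350 lower. At 24 h, 268 of the 350 were again lower and 7 were higher, while 57 of the 70 were again higher and 0 were lower. Independent calls would share 67.1 and 8.73. Each gene has the same spread for all times in this fit, however, so the calls are not independent and these values are no fair baseline. Camera gave an adjusted p of 8.7e-16 for the feedback list, 3.9e-20 for the MAPK activity list and 8.3e-10 for the immediate-early list, and the adjusted p was 0.160, 0.234 and 0.160 with an estimated correlation. The count of 420 was 205 without the PD184352 6 h array, 212 without the PLX4720 6 h array, 801 without the PD184352 24 h or the PLX4720 24 h array, and 253 with no filter on dim genes.

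At 2 h, 9 genes fell and 2 rose. The falls were SPRY4 (−1.94, SE 0.25), the stress-response gene IER3 (−1.58, SE 0.13), ERRFI1 (−0.91, SE 0.12), the transcription factor genes EGR1 (−0.83, SE 0.11), FOSL1 (−0.73, SE 0.10) and HOXB2 (−0.71, SE 0.09), PHLDA1 (−0.69, SE 0.09), and 2 further genes, RGS16 (−0.68, SE 0.09) and TFAP2C (−0.62, SE 0.09), named here after their values were seen. DUSP6 was at −2.88 (SE 0.56, adjusted p = 0.157) and SPRY2 at −2.44 (SE 0.51, adjusted p = 0.186), and neither passed. Their SE includes the difference between compounds at the later times, which was 1.84 for DUSP6 and 1.62 for SPRY2 at 24 h and 0.83 for both at 6 h. The rises were FKBP5, a chaperone gene (1.00, SE 0.12), and the antisense gene DNAJC27-AS1 (0.82, SE 0.11). For both genes the DMSO 2 h array read lower than the later DMSO arrays. FKBP5 stood at 6.07 (log2) there, against 6.81 at 6 h and 6.66 at 24 h, and DNAJC27-AS1 at 6.60, against 7.18 and 7.11.

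All 9 genes lower at 2 h were also lower at 6 h, and 8, without RGS16, were lower at 24 h. Independent calls would share 0.246 and 1.72, but here too each gene has 1 spread for all times, so these values are no fair baseline. Of the feedback list 1 gene fell at 2 h over all genes and 8 adjusted over the list alone (camera adjusted p = 5.4e-11, and adjusted p = 0.273 with an estimated correlation). Of 21 immediate-early genes 3 fell, and 13 adjusted over the list alone (camera adjusted p = 2.5e-12, and adjusted p = 0.111 with an estimated correlation). The count of 11 was 0 without the PD184352 2 h or the PLX4720 2 h array, 3 without the PD184352 6 h or the PLX4720 6 h array and 95 without the PD184352 24 h or the PLX4720 24 h array. It was also 0 after quantile normalization, 1 with no filter on dim genes and 35 with the stricter filter.

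**Figure D2:**
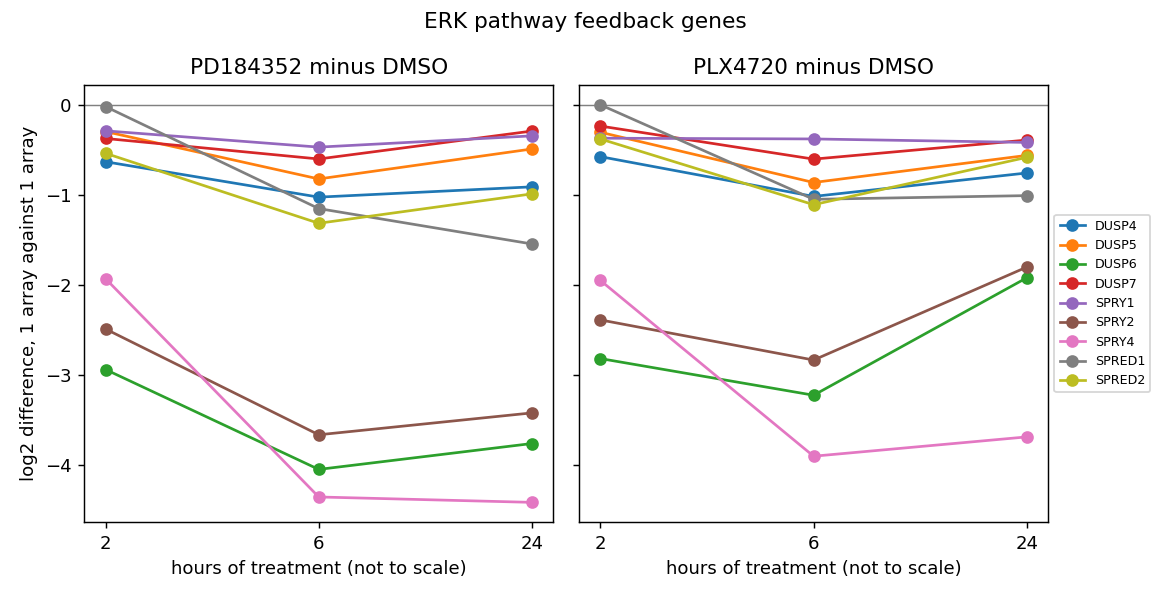
Log2 difference from the DMSO array of the same time (vertical axis) for the 9 ERK feedback genes called at 24 h, by hours of treatment (horizontal axis, not to scale), with PD184352 on the left and PLX4720 on the right. Each point is 1 array against 1 array, and DUSP6 stands at −3.77 with PD184352 and −1.92 with PLX4720 at 24 h.

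Averaged over the 3 times, 17 genes were called with either inhibitor, all lower, and each was lower in 6 of 6 inhibitor arrays. The 6 of 6 is no added support, since this fit favours genes whose differences are alike over the times. Both compounds also share each DMSO array, and 2839 of the 12785 genes had 1 sign in all 6 differences. The 10 largest falls were in DUSP6 (−3.12, SE 0.28; transcript cluster 3464860), SPRY2 (−2.77, SE 0.25; transcript cluster 3519309), IER3 (−1.63, SE 0.10), EGR1 (−1.12, SE 0.10), the repressor SNAI1 (−0.93, SE 0.11), the pseudokinase TRIB1 (−0.90, SE 0.08), HOXB2 (−0.90, SE 0.08), DUSP4 (−0.82, SE 0.08), MYC (−0.78, SE 0.06) and PHLDA1 (−0.74, SE 0.08). All 17 were called at 6 h and at 24 h, and 4 at 2 h. For PD184352 alone 6 genes were called, among them DUSP6 (−3.59, SE 0.32), SPRY2 (−3.20, SE 0.29), IER3, MYC and TRIB1, and for PLX4720 alone 1, IER3. Unadjusted p-values below 0.05 numbered 2589, 2294 and 1573. In 10 lists the shift was downward and in 3 upward by camera, and none of the 13 held with an estimated correlation, where the smallest adjusted p was 0.242. In this fit the estimated correlation, 0.967 for DNA replication and 0.987 for mitosis, also takes in the lists' own change with time.

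The count of 17 was 0 without the DMSO 6 h, PD184352 6 h, PD184352 24 h, PLX4720 2 h or PLX4720 6 h array, 3 without PLX4720 24 h, 4 without PD184352 2 h, 107 without DMSO 24 h and 545 without DMSO 2 h, 28, 0 and 200 without the arrays of 2, 6 and 24 h, and it was 0 after quantile normalization and 1804 with array weights, whose estimation did not converge. For PD184352 the 6 became 0 without any 1 of DMSO 6 h, the 3 PD184352 arrays, PLX4720 2 h or PLX4720 6 h, 3 without PLX4720 24 h, 81 without DMSO 24 h, 388 without DMSO 2 h, and 0 and 102 without the arrays of 6 h and 24 h. For PLX4720 the count was 0 without DMSO 6 h or any of the 6 inhibitor arrays, 24 without DMSO 24 h, 165 without DMSO 2 h, and 6, 0 and 41 without the arrays of 2, 6 and 24 h. The 13 lists became 7 without DMSO 24 h and 8 without all 24 h arrays.

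PD184352 and PLX4720, given at different doses, were compared directly. No gene was called different between them over the 3 times by limma (0 of 12785, smallest adjusted p = 1.00), and 169 genes had an unadjusted p below 0.05, where 639 would be expected by chance. Responses that vary with time enter the spread of this fit, which makes it conservative. A fit on the 6 inhibitor arrays alone, chosen after seeing the data, leaves shared responses to the time block: it also called 0 genes by limma (smallest adjusted p = 0.194), with 556 at an unadjusted p below 0.05, and gave DUSP6 an adjusted p of 0.429 and SPRY2 of 0.381. In the first fit, the 95% interval of the difference lay within 2-fold for 99.4% of genes. The difference, PD184352 minus PLX4720, was −0.93 for DUSP6 (95% interval −1.69 to −0.17) and −0.85 for SPRY2 (interval −1.54 to −0.16), and neither passed. At 24 h DUSP6 was at −3.77 with PD184352 and −1.92 with PLX4720, and SPRY2 at −3.43 and −1.80, with no test at a single time. Of the genes called at 24 h, 70.2% of the higher and 73.8% of the lower ones changed more with PD184352. At 6 h these shares were 78.6% of 70 higher and 48.0% of 350 lower genes, and at 2 h 50% of 2 and 55.6% of 9.

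Across genes, which are not independent replicates, the changes with both inhibitors correlated at 0.636 at 2 h, 0.838 at 6 h and 0.955 at 24 h. Both share a DMSO array, which with no effect at all gave 0.499 to 0.502 in simulations. The covariance was 0.0140, 0.0372 and 0.173, against a simulated 0.00711, 0.00717 and 0.00709. The share of genes with the same sign for both inhibitors was 67.0% at 2 h, close to the simulated 66.6%, and 75.1% at 6 h and 84.0% at 24 h, against 66.8% and 66.6%. Single DMSO arrays could not be divided, so part of the excess may come from the shared array.

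**Figure D3:**
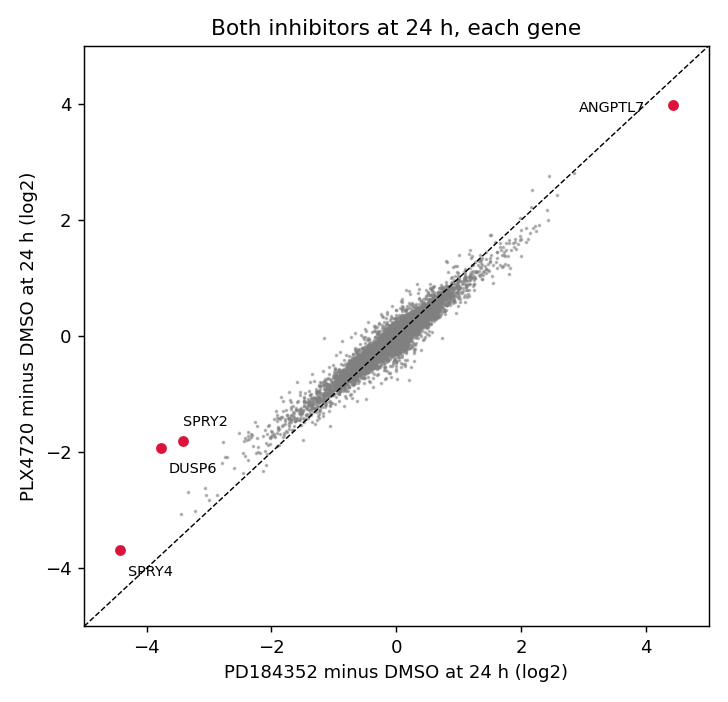
Log2 difference from the DMSO 24 h array with PD184352 (horizontal axis) and PLX4720 (vertical axis) for each of 12785 genes (grey), with 4 genes marked in red and the dashed line marking equal change. DUSP6 and SPRY2 lie above the line, at −1.92 and −1.80 with PLX4720 against −3.77 and −3.43 with PD184352.

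The change differed between times for 1904 genes by limma's F-test. Of these, ETV4 (−2.78, 24 h minus 2 h change), ETV5 (−2.76), LPL (−2.75), MRGPRX3 (−2.68) and MRGPRX4 (−2.67) moved furthest down, and ANGPTL7 (4.10), P2RX7 (2.93), ITGA2 (2.64), CCN3 (2.49) and the AP-1 gene JUN (2.45) furthest up. For DUSP6, SPRY2, IER3, EGR1, MYC and DUSP4 the difference between times did not pass. These genes were called in the mean over the 3 times, a fit that favours changes alike over the times. For DUSP6 and SPRY2 the difference between compounds also widens the SE. Their not passing therefore does not show a steady change.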

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

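The tests of the DMSO 24 h array, of a distortion that follows intensity and of array noise at 24 h, all tests of a weaker PLX4720 response and both glucocorticoid tests were chosen after the results were seen, another on time in culture was dropped because each contrast already uses DMSO of the same time, and another on dim genes because these respond too little to decide. The readings of the matched and glucocorticoid percentile tests, first taken to exclude their explanations, were also changed to undecided after the results were seen. The change with either inhibitor differed between times for 1904 genes by limma's F-test, which takes 6 h minus 2 h and 24 h minus 2 h together. The values that follow are the 24 h minus 2 h part, which was not tested by itself, so a gene can have passed through its 6 h change. Among named genes, the 24 h change minus the 2 h change (log2) was negative for ETV4 (−2.78), ETV5 (−2.76), LPL (−2.75), MRGPRX3 (−2.68), MRGPRX4 (−2.67), CDK1 (−2.34), ETV1 (−2.15), SLC7A11 (−2.14), SPRY4 (−2.11), CDC45 (−2.07), MCM10 (−2.04), ERRFI1 (−1.98), CCNE2 (−1.95), CDC25A (−1.89), RFC3 (−1.86), TTK (−1.78), KIF11 (−1.77), PMAIP1 (−1.73), TGFA (−1.73), NUF2 (−1.60), CHAC1 (−1.58), CCND1 (−1.56), POLE (−1.51), MEOX2 (−1.43), SPRED1 (−1.27), FKBP5 (−1.24), RRS1 (−1.21), NOLC1 (−1.10), CDK6 (−1.10), SLC7A5 (−1.07), NT5E (−1.05), EPHA4 (−1.04), RBL1 (−1.03), POLR1B (−0.82), PHGDH (−0.80), HPRT1 (−0.74), RRP1B (−0.73), KLF4 (−0.68), DNAJC27-AS1 (−0.63), IGF1R (−0.60), GLA (−0.60), FOSL1 (−0.42), DUSP5 (−0.23), ELK3 (−0.19). It was positive for FBXO32 (0.35), KDR (0.36), MLANA (0.50), EDNRB (0.58), CTSA (0.61), INSIG1 (0.66), IRF9 (0.72), ARHGEF17 (0.79), TM7SF2 (0.80), IFIT2 (0.81), CD68 (0.85), TP53I3 (0.95), CSF1 (0.98), CITED2 (1.04), SESN3 (1.13), DDR1 (1.30), MMP15 (1.38), BMF (1.502), CCL2 (1.71), SLITRK6 (1.73), TP53INP1 (2.07), SEMA3D (2.43), JUN (2.45), CCN3 (2.49), ITGA2 (2.64), P2RX7 (2.93), ANGPTL7 (4.10).

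Rows with no single gene name lie outside the main tests. Of the 7355 such rows above the level set for named genes, 0 changed against DMSO at 2 h, 13 at 6 h and 652 at 24 h by limma, or 8.86% at 24 h against 31.6% of named genes.

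The response was larger at 24 h than at 2 h or 6 h (4045 genes against 11 and 420). With the DMSO 6 h array as the 24 h control, 84.2% of the genes called at 24 h were called in the same direction, which argues against the DMSO 24 h array as the whole cause. Noise of the single 24 h inhibitor arrays would widen the difference between compounds, but its SD at 24 h was 1.06 times that at 2 h, against 3.12 times for the mean change. A distortion of both 24 h inhibitor arrays that follows intensity is argued against as the whole cause, as far as quantile normalization would remove it. That normalization kept 94.3% of the genes called at 24 h in the same direction, with an SD ratio of 3.34. It was a small correction, which moved the 24 h changes by an SD of 0.04. At 2 h it left 0 genes called, but the 2-fold counts stayed at 5 with PD184352 and 6 with PLX4720. At 24 h, 124 genes were at least 2-fold higher and 295 at least 2-fold lower with both compounds, and 0 went 2-fold opposite ways. Between DMSO 24 h and DMSO 6 h, 1 gene differed 2-fold. These values argue against a difference of 1 culture alone. A longer inhibition, which the design names, remains a hypothesis, since 1 array per treatment and time cannot set it apart from a difference that both 24 h inhibitor cultures share.

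At 24 h, DUSP6 and SPRY2 were less low with PLX4720 than with PD184352. PLX4720 minus PD184352 was 1.84 for DUSP6 and 1.62 for SPRY2 at 24 h, 0.83 for both at 6 h, and 0.12 and 0.10 at 2 h. Compression over the whole range of tested levels on the PLX4720 24 h array is argued against by a slope of 0.999 over 7038 genes that changed little. The dimmest genes were not in it, and the 1st percentile of intensity was 7.19 on that array against 6.79 on PD184352 24 h. Compression at the low end alone is therefore not decided. For a response to PLX4720 that is weaker in all genes alike, the median difference of the 9 called feedback genes lay at percentile 99.83 of random lists, but 3 of the 9, DUSP6, SPRY2 and SPRY4, had no genes of like change to be matched with, so the test decides nothing. For a weaker response in proportion (slope 0.855), DUSP6 and SPRY2 lay 1.30 and 1.13 above that line. The other 2441 genes that fell lay at most 0.57 above it, and the residual SD was 0.238 among the 50 of these with a PD184352 change of −2 or lower. DUSP6 and SPRY2 thus lay further above the line than the rest, but they were picked for their gap on the same arrays. Their residuals describe that gap and do not test its cause. For the 9 genes as a list the median residual lay at percentile 99.36, but 3 of the 9 lay below the line, so whether the list as a whole departs from it stays open, as does any effect of the lower dose on DUSP6 and SPRY2 in particular, which was not tested.

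FKBP5 and DNAJC27-AS1 were higher at 2 h. A low reading of both genes on the shared DMSO 2 h array is a candidate explanation: the 2 h inhibitor arrays lay only 0.34 (FKBP5) and 0.27 (DNAJC27-AS1) above the mean of the later DMSO arrays, under the 0.5 set before this comparison. DNAJC27-AS1 also read above DMSO with PD184352 and PLX4720 at 6 h (7.38 and 7.36 against 7.18) and 24 h (7.26 and 7.35 against 7.11). It was not called at these times, FKBP5 was not higher there, and the DMSO 2 h array does not bear on these smaller gaps. A glucocorticoid-receptor response that moves its responsive genes by about 1.00, as FKBP5 moved against DMSO 2 h, is argued against. The highest 2 h change among 13 others was 0.12, and their median was −0.05 (SD 0.28). A smaller response, such as the 0.34 of FKBP5 over the later DMSO arrays, is not argued against by that spread. The 13 genes are also not free of the inhibitors' own effect, since ERRFI1 among them fell (−0.91). A response limited to FKBP5 and few other genes stays open, since the median of the 13, at percentile 23.3 of random lists, does not bear on it. No other biological explanation was tested.

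Of the 81 divisions of the 9 arrays into 6 and 3 that could be fitted, with both inhibitors as 1 group, the real 1 called 97 genes (17 with the inhibitors kept apart) and the highest of the others 0. The other divisions put treated and DMSO arrays on the same side, so a treatment effect widens their spread and makes calls unlikely. Many of them also do not take 1 array of each time. The 0 therefore does not exclude a chance division or a difference between cultures. For PD184352 (6 genes, highest other 0), PLX4720 (1 gene, highest other 0) and PD184352 against PLX4720 (0 genes, in all 10), the 10 divisions of 6 arrays are too few for a share under 0.05.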

How the results depend on the processing

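Other pseudocounts, a fit without the 24 h arrays, DMSO 6 h as the 24 h control and a fit on the inhibitor arrays alone were chosen after seeing the data. Of 234 recomputed counts 147 stayed within 1.5 times. The 24 h count stayed within it in all but the threshold of 0.01, and the count between compounds was 0 throughout. Of 10988 recomputed values of 132 named genes, 10414 kept their direction and side of the threshold, 309 lost the call, 261 gained it and 4 reversed: PLK3 at 24 h with averaged rows (0.12), and RPS6KA2 (0.13), PMEL (−0.31) and AJUBA (−0.050) at 24 h with DMSO 6 h as control. In the second fit, leaving out either 24 h inhibitor array takes 24 h out of the spread. For the counts at 2 h and 6 h it is therefore the same test as leaving out all 24 h arrays. These counts rose once the difference between the compounds at 24 h was out of the spread. For the other counts that moved, the cause was not tested. With no filter on dim genes the counts were 1 for PD184352, 0 for PLX4720, 1 at 2 h and 253 at 6 h, and 14 and 19 genes were 2-fold apart on the PD184352 and PLX4720 2 h arrays. The filter of 50% gave 14 for PD184352 and 35 at 2 h. Quantile normalization gave 0 for either inhibitor, PD184352, PLX4720 and 2 h. At 2 h, median centring gave 24, robust moderation 24 and log2(value + 16) 23. A variance trend gave 0 for PLX4720. Array weights, whose estimation did not converge, gave 1804 for either inhibitor, 1936 for PD184352, 547 for PLX4720, 7 lists and 1 at 2 h. The threshold of 0.01 gave 0 for either, PD184352 and PLX4720, 1 at 2 h, 178 at 6 h, 2607 at 24 h and 872 for the difference between times. Without the time block there were 9 for either and 6 for PLX4720. Camera with an estimated correlation called 0 lists and fry 6. Without the 24 h arrays there were 95 at 2 h and 801 at 6 h. At 1.5-fold, single-array counts were 50, 243 and 1698 with PD184352 and 38, 242 and 1372 with PLX4720.

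Leaving out 1 array or 1 time, with a lone array assumed to vary like the rest, gave ranges of 0 to 545 for either inhibitor, 0 to 388 for PD184352, 0 to 165 for PLX4720, 7 to 14 lists, 0 to 95 at 2 h, 205 to 801 at 6 h, 3377 to 4066 at 24 h and 1466 to 2393 for the difference between times. A time without its DMSO array, or the difference between times without it, could not be estimated and was not run. Arrays were matched by time through the time block. Arrays have no counting depth, and the 4262 dimmest genes were not tested.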

Other observations

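Other lists fixed before the data were examined moved less or in both directions at 24 h, by limma over all genes, and the SE of each value given was between 0.09 and 0.24. Of 18 glycolysis genes 7 fell and 1 rose, with PFKFB3 at −0.77 and HK2 at −0.59. Of 11 ETS factors 5 fell and 2 rose, with ETV1 at −2.43. Of 11 growth factor genes 5 rose and 2 fell, the latter TGFA (−2.16) and VEGFA (−0.97), and the list's median (0.17) and mean (−0.08) differ in sign. Of 10 chemokine and cytokine genes 2 rose, CCL2 (1.63) and CSF1 (0.70). Of 14 receptor tyrosine kinases 4 rose and 4 fell (5 and 5 adjusted over the list alone), with DDR1 at 1.07 and EPHA4 at −1.30. In the BCL2 family BMF rose (1.85) while PMAIP1 (−2.41) and BCL2 (−0.63) fell. Of 14 interferon response genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with IFIT2 at 0.76 and OAS3 at −0.39. Of 17 cholesterol synthesis genes 4 rose, with TM7SF2 at 0.83 and INSIG1 at 0.64. Of 12 matrix protease genes 4 rose and 5 fell, with MMP15 at 1.31 and PLAT at −1.19. Of 18 YAP and TEAD targets 6 rose and 3 fell, with NT5E at −1.35. Of 13 lysosome and autophagy genes 3 rose and 2 fell (5 and 2 adjusted over the list alone), with CTSA at 0.51 and GLA at −0.56. For the other lists here, the counts adjusted over the list alone were equal to those over all genes. Of 8 CDK inhibitor and pocket protein genes 1 fell, RBL1 (−1.12). Of 10 RAS-RAF-MEK-ERK components 3 fell, RPS6KA1 (−0.34), RPS6KA3 (−0.33) and RPS6KA2 (−0.30, but 0.13 with DMSO 6 h as control). By camera, ETS factors (adjusted p = 0.0266, and adjusted p = 0.556 with an estimated correlation) and interferon response genes (adjusted p = 0.0266, and adjusted p = 0.428 with an estimated correlation) were called at 24 h and none of the other lists here. The median and the mean also differ in sign for matrix proteases (−0.01 and 0.01), the BCL2 family (0.00 and −0.10) and fibroblast markers (0.02 and −0.10).

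Markers of other cell types gave these calls at 24 h: 0 of 5 keratinocyte genes, 1 higher (FAP, 0.53) and 1 lower (MEOX2, −1.64) of 9 fibroblast genes, and 1 higher (CD68, 0.73) of 6 leukocyte and endothelial genes. Of all genes tested, 31.6% were called at 24 h. The median levels (log2) of the measured genes in these 3 lists were 6.69, 6.38 and 5.93, against a cut of 6.21 for testing. The lists are thus too short and dim to show that such markers responded less than other genes. Of 12 reference genes 1 rose and 2 fell, HPRT1 (−0.70) and TUBB (−0.35).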
